A study of Homo sapiens with 16 samples.

How the data were processed

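RNA was measured on 16 one-colour Affymetrix U133 Plus 2.0 arrays, 1 per sample, from 2 human mammary cell lines. MCF10A is an immortalized, non-tumorigenic mammary epithelial line, and MDA-MB-231 is a breast cancer line. Per the labels' protocols, cells were seeded at low confluence in medium with 17.5 mM glucose and received 50 mM 2-deoxy-glucose (2DG), a glucose analogue that blocks glycolysis, or the same amount of water as vehicle. They were harvested after 24 h. Each of the 4 groups held 4 biological replicates, which the series' design text calls independent and run in parallel. The media of the lines differed in serum and supplements, per the labels' protocols: the MCF10A medium held horse serum, insulin, epidermal growth factor, cholera toxin and hydrocortisone, and the MDA-MB-231 medium fetal bovine serum. Line and medium could therefore not be separated.

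The deposited values were log2 probe set summaries made by the authors with RMA (robust multi-array average: background correction, quantile normalization and summary of the probes of a set), per the submitters' processing notes, and biotin-labelled RNA was made with a 3' IVT kit, per the labels' protocols. The version of RMA, and whether all arrays were normalized together, were not given in the sources used here. The deposited table held 54675 probe sets, 62 of them controls, with values from 2.38 to 15.15 rounded to 2 decimals. The array medians lay between 6.17 and 6.22 and the quartiles of the arrays within 0.08 of each other. RMA values carry no call of signal over background and compress small signals, so changes into or out of the lowest values are understated. The number of arrays limits the precision. Labelling from the 3' end makes values depend on RNA integrity, which was followed with the 3' and 5' actin and GAPDH control probe sets.

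Probe sets were named through GEO's platform annotation as supplied here, which named genes for 42898 of them: 1801 had several genes and were left out, and 11777 had no row and were not used here. The gene symbols were looked up by Entrez gene number in the RefSeq table of assembly GRCh38.p14. This found 41037 of the 41091 probe sets with 1 gene and changed no symbol, and 54 kept the name of the annotation. The arrays name no genome build, so no coordinates are given. Each of the 19775 genes was represented by its probe set with the highest mean over all arrays. Of the 141 genes named by the rule below, other probe sets were compared for 116 of 180 pairs of a gene and a comparison. In 19 of these at least 1 other probe set had the opposite sign, and in 5 of them by over 0.5. The size of a change depended on the probe set: the mean of all probe sets differed from the printed value by over 1.5 times for 51 of the 180 pairs and that without shared probe sets for 23 of 145, so the order of the largest changes holds for the brightest probe sets only. For the genes named outside this rule with values, other probe sets existed for 13 of 15 pairs, and in 3 of these at least 1 had the opposite sign. KLRC3, TIMM23B and SPANXB1 have near-identical copies elsewhere in the genome, and their values are uncertain for that reason.

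The log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 4 group means over all 16 arrays, which left 12 residual degrees of freedom per gene. The comparisons were 2DG against vehicle in each line, the difference of these responses (MDA-MB-231 minus MCF10A) and the lines on vehicle. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and a strong call also had a log2 change of at least 1 in size. The errors given are standard errors (SE) of the fit or standard deviations (SD) over the 4 arrays of a group. No filter on dim genes was applied.

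Before the data were examined, 26 gene lists with 811 genes were fixed, of which 72 genes had no value and were not analysed here. Lists were tested with camera in limma, which compares the members with all other genes, at a preset correlation of 0.01 and adjusted over the lists of a comparison. The same lists were tested with an estimated correlation and with fry. Fry's one-way and mixed tests ask whether the members of a list move and do not compare them with other genes. Members were also counted with p adjusted over the list alone. The named genes followed a rule fixed at the same time. It took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, for each line and for the vehicle comparison. It added the 6 largest differences of response each way, 1 of which is not reported here, the 2 called members with the largest change per list and line, and 13 genes named in advance (CCN2, CCN1, ANKRD1, AMOTL2, YAP1, WWTR1, TXNIP, ARRDC4, HSPA5, DDIT3, TRIB3, HK2 and SLC2A1).

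The procedure was tested on simulated data drawn from the real residual SDs of the 19775 genes, with the vehicle means of a line used for both of its groups. In it 200 genes were changed, far fewer than were called in the real data. In the simulated MCF10A comparison, 40% of the genes changed by 0.25, 90% of those changed by 0.5 and 100% of those changed by 1 or 2 were recovered, with 7 calls among 19537 unchanged genes. In the simulated MDA-MB-231 comparison the shares were 52%, 90%, 100% and 100%, with 5 calls among 19575 unchanged genes. For the simulated difference of responses over the 19775 genes they were 22%, 74%, 98% and 100%, with 8 calls among unchanged genes. A list shifted by 0.3 in the simulated MCF10A comparison was called, and 0 other lists were. No list was shifted or tested in the simulated MDA-MB-231 comparison. Genes were drawn independently, whereas the estimated correlation of the real lists reached 0.1876, so list calls whose members move together were not checked.

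The alternatives were a replicate block, centring or quantile normalization, a filter on dim genes, the mean of all probe sets, leaving out probe sets shared between transcripts (names ending in _x_at or _s_at), the variance model, array weights, only the 8 arrays compared, an adjusted p under 0.01, each array left out in turn, and for lists an estimated correlation and ranks. After the data were seen, the actin 3'/5' ratio as a covariate, the list counts without MDA-MB-231 vehicle replicate B and the YAP signature without members of the cell division lists were added. Replicates were compared before averaging: 0 pairs of arrays were identical, and the correlations within groups lay between 0.998 and 0.999.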

Results

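Gene expression was measured on 16 arrays from MCF10A and MDA-MB-231 cells treated for 24 h with 50 mM 2DG or vehicle, with 4 replicates per group. The series asks how glucose metabolism regulates gene expression in mammary cells, and 2DG was the means of inhibiting it. The transcriptional regulators YAP and TAZ, encoded by YAP1 and WWTR1, and their targets were among the genes fixed in advance. The median SD of a gene over the 4 arrays of a group was 0.0759 in MCF10A vehicle, 0.0787 in MCF10A 2DG, 0.0858 in MDA-MB-231 vehicle and 0.0794 in MDA-MB-231 2DG. All changes below are differences of log2 values.

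The actin 3'/5' control ratio, a sign of RNA integrity, is given in log2 (3' minus 5' value). It was 0.392 ± 0.067 (SD, n = 4) in MCF10A vehicle and 0.55 ± 0.0678 in MCF10A 2DG. In MDA-MB-231 it was 0.598 ± 0.331 on vehicle and 1.03 ± 0.0714 with 2DG. Vehicle replicate B of MDA-MB-231 stood at 1.09, beside a mean of 0.433 for the other 3 vehicle arrays. The actin ratio was thus higher with 2DG in both lines, by more in MDA-MB-231, and the responses given below were measured alongside it. The GAPDH 3'/5' control ratio (log2) hardly moved in MCF10A, at 0.155 ± 0.0129 on vehicle and 0.17 ± 0.0141 with 2DG. In MDA-MB-231 it was 0.215 ± 0.124 on vehicle and 0.348 ± 0.0556 with 2DG.

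**Figure D1:**
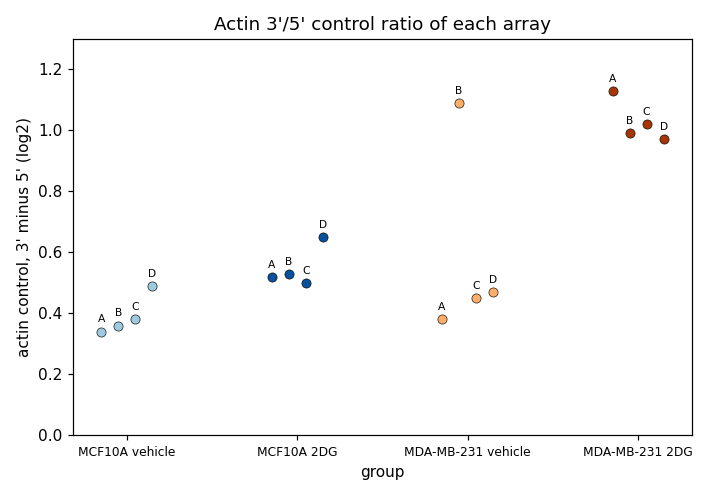
The actin 3' minus 5' control value (log2) of each array, by group, with the replicate letter above each point. In MDA-MB-231 the 2DG arrays lie between 0.97 and 1.13, and vehicle replicate B lies at 1.09 beside vehicle arrays from 0.38 upward.

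In MCF10A, 2DG lowered the genes of cell division. All 41 measured members of the G2/M and mitosis list fell (41 adjusted over the list alone), with a median change of -3.29, as did 44 of 45 members of the DNA replication and S phase list (44 adjusted over the list alone), with a median of -2.32. MCM10, a factor of replication initiation, fell by 6.90 ± 0.0454 (SE, n = 4 per group) on its brightest probe set and changed by -4.925 and -4.75 on its other probe sets, and RRM2, a subunit of ribonucleotide reductase, fell by 5.88 ± 0.0748. BUB1, a kinase of the spindle checkpoint, fell by 4.56 and HMMR, a mitotic spindle protein, changed by -5.00. Both lists were shifted down in camera (adjusted p = 3.27e-32 and 6.56e-29, and 0.00272 for both with an estimated correlation).

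Further large falls in MCF10A were those of SPC25, a kinetochore protein (-5.64), the cyclin CCNE2 (-5.48), the DNA polymerase subunit POLE2 (-5.335), DTL (-4.87) and the exonuclease EXO1 (-4.84). The largest rises were PDK4, a kinase that inhibits pyruvate dehydrogenase, by 5.37 ± 0.0528, and ABCG1, a sterol exporter, by 5.22 ± 0.0759. CAPN8 rose by 4.90, CACNA2D3 by 4.57, KLRC3 by 4.52, TSC22D3, a glucocorticoid-induced leucine zipper protein, by 4.51, BLNK by 4.30 and CFAP53 by 4.21. A dim further probe set of TSC22D3, the only probe set left for this gene without those shared between transcripts, fell by 0.33 (adjusted p = 0.0388). The limma adjusted p of these 16 genes were at most 1.77e-14. Without shared probe sets ABCG1 rose by 1.575.

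Stress response genes rose in MCF10A. Of 38 members of the ATF4 and integrated stress response list, 33 rose and 3 fell (33 and 4 adjusted over the list alone), with a median of 0.97. ATF3 rose by 3.70 and DDIT3, which encodes the CHOP factor, by 3.10, and TRIB3 rose by 2.02. Of 34 members of the unfolded protein response list, 27 rose and 3 fell, both overall and adjusted over the list alone, with a median of 0.56. HERPUD1 rose by 2.72, the chaperones DNAJB9 by 2.50 and HSPA5, also called BiP, by 0.81. Of 25 NRF2 targets, 20 rose and 2 fell (20 and 2 adjusted over the list alone), among them the aldo-keto reductases AKR1C1 by 3.78 and AKR1C3 by 3.01. Camera called these 3 lists (adjusted p = 2.57e-11, 2.68e-07 and 3.91e-08, and 0.00438, 0.01 and 0.00354 with an estimated correlation).

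All 39 measured ribosome biogenesis genes fell in MCF10A (39 adjusted over the list alone), with a median of -0.83. LYAR fell by 1.57 and POLR1B, a subunit of RNA polymerase I, fell by 1.54 (camera adjusted p = 9.19e-18, and 0.00787 with an estimated correlation). Of 22 members of the cytosolic heat shock response list, 5 rose and 16 fell, also adjusted over the list alone, with HSPE1 down at -1.81 and CRYAB up by 1.89 (camera adjusted p = 0.000264, and adjusted p = 0.0638 with an estimated correlation). Of 39 autophagy and lysosome genes, 26 rose and 4 fell, also adjusted over the list alone, among them GABARAPL1 by 2.08 and the kinase ULK1 by 1.78 (adjusted p = 2.6e-05, and adjusted p = 0.17 with an estimated correlation). Of 26 p53 targets, 19 rose and 5 fell, also adjusted over the list alone, with TP53INP1 up by 3.34 and SPATA18 by 1.58 (adjusted p = 0.00308, adjusted p = 0.17 with an estimated correlation, and 0.133 without shared probe sets). Of 27 hypoxia and HIF targets, 19 rose and 5 fell, also adjusted over the list alone, with STC2 up by 2.398 and ANGPTL4 down at -1.89 (adjusted p = 0.000483, and adjusted p = 0.206 with an estimated correlation).

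Genes of glucose metabolism fell in part in MCF10A. Of 22 glycolysis and glucose uptake genes, 4 rose and 15 fell (4 and 16 adjusted over the list alone). Hexokinase HK2 fell by 2.29 ± 0.057 and phosphofructokinase PFKM fell by 1.17, while the glucose transporter SLC2A1 rose by 0.16 ± 0.0375. The list was called (adjusted p = 0.000987), with an adjusted p = 0.17 with an estimated correlation and 0.178 without shared probe sets. TXNIP and ARRDC4, arrestins that restrain glucose uptake and respond to hexose phosphates, rose by 2.59 ± 0.0329 and 3.26 ± 0.0493. Of 56 oxidative phosphorylation genes, 8 rose and 36 fell (8 and 38 adjusted over the list alone), among them ATP5MC1 (-1.56) and NDUFB3 (-0.85) (adjusted p = 0.00027, and adjusted p = 0.283 with an estimated correlation).

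The targets of YAP and TAZ went both ways in MCF10A. Of 21 core targets, 10 rose and 9 fell (10 and 9 adjusted over the list alone), and camera did not call the list (adjusted p = 0.772, median -0.08). CCN2 fell by 0.62 ± 0.0502, CCN1 fell by 0.68 ± 0.0466 and AMOTL2 fell by 0.75 ± 0.0341 (limma adjusted p = 1.26e-08, 1.64e-09 and 7.63e-12), and FJX1 fell by 2.79 and NT5E fell by 1.88. ANKRD1, at 4.30 on vehicle and 4.14 with 2DG, did not pass (change -0.16, adjusted p = 0.56). The wider conserved signature of YAP had 9 of 50 members that rose and 33 that fell, also adjusted over the list alone, with a median of -0.65 (adjusted p = 8.63e-07, and adjusted p = 0.0638 with an estimated correlation). Its largest falls, HMMR and SHCBP1 (-4.807), are genes of mitosis and proliferation, and 6 of its members are in the G2/M list. WWTR1 fell by 1.01 ± 0.0388. YAP1 did not pass (change -0.09, adjusted p = 0.107, and 0.0411 with eBayes with trend and robust). Its other probe sets had the opposite sign, 1 of them at 0.78, and the mean of all its probe sets rose by 0.286 (adjusted p = 3.87e-06), so its direction depended on the probe set.

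**Figure D2:**
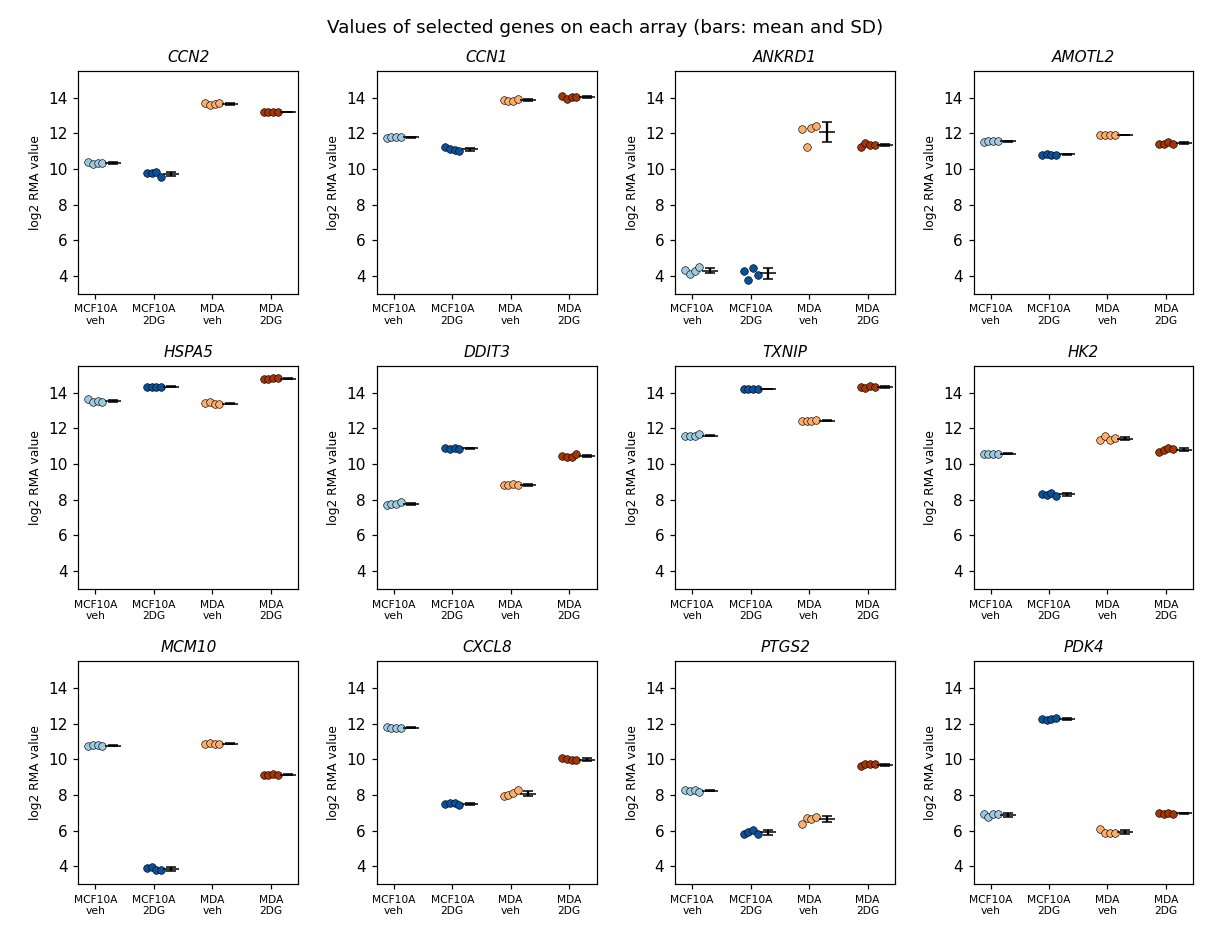
Log2 RMA values of 12 genes on each of the 4 arrays per group, with mean and SD beside the points; veh is vehicle. CXCL8 and PTGS2 fell with 2DG in MCF10A and rose in MDA-MB-231, and ANKRD1 lay near the bottom of the scale in MCF10A.

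Other lists in MCF10A were called at the preset correlation alone. Of 27 NF-kB and inflammatory genes, 7 rose and 16 fell (7 and 17 adjusted over the list alone), with the chemokines CXCL8 at -4.257 and CXCL1 at -3.63 (adjusted p = 0.0235, adjusted p = 0.0731 with an estimated correlation, and 0.085 without dim genes). Of 29 MAPK immediate-early and feedback genes, 6 rose and 18 fell, also adjusted over the list alone, with EGR1 up by 2.22 and SPRY1 down at -2.12 (adjusted p = 0.00251, and adjusted p = 0.283 with an estimated correlation). Of 29 epithelial and basal markers, 16 rose and 4 fell, also adjusted over the list alone, with KRT16 up by 1.95 and ELF3 by 1.71 (adjusted p = 0.00575, and adjusted p = 0.17 with an estimated correlation).

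The remaining lists were not called in MCF10A, and their members moved both ways. Aminoacyl-tRNA synthetases had 6 that rose and 9 that fell (WARS1 1.62, FARSB -1.48; adjusted p = 0.641). The hexosamine and N-glycosylation list had 18 and 16 (OGT 1.64, OGA 1.29; adjusted p = 0.772), and the pentose phosphate list 4 and 5 (PRPS2 -1.15, RPIA -1.13; adjusted p = 0.426). The cholesterol list had 8 and 7 (PMVK -1.56, ACAT2 -1.08; adjusted p = 0.804) and fatty acid synthesis 5 and 4 (ACSS2 1.56, ELOVL6 -1.37; adjusted p = 0.89). Interferon-stimulated genes had 15 and 11 (RSAD2 1.78, SAMD9 1.47; adjusted p = 0.438), extracellular matrix and integrins 14 and 16 (THBS1 -2.61, MMP9 -2.49; adjusted p = 0.618). Mesenchymal markers had 11 and 8 (S100A4 2.21, ZEB2 2.18; adjusted p = 0.641) and luminal markers 6 and 4 (AGR2 3.18, XBP1 1.90; adjusted p = 0.711). Counts adjusted over the list alone were the same for these lists. For the synthetases, hexosamine, cholesterol, fatty acid and luminal lists, the median differed in sign from the mean or from the test.

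Over all genes, 5732 were higher and 4989 lower with 2DG in MCF10A, of 19775 tested with limma, and 1065 and 1149 of these were strong calls. The median change of all genes was 0.0225 and the median SE 0.0665. Camera called 7 lists up and 9 down, and 3 and 3 with an estimated correlation.

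In MDA-MB-231, stress response genes rose with 2DG. Of 38 members of the ATF4 list, 32 rose and 2 fell, also adjusted over the list alone, with a median of 1.15; CTH, an enzyme of cysteine synthesis, rose by 2.92, ATF3 by 2.88, TRIB3 by 1.90 and DDIT3 by 1.63. Of 34 unfolded protein response genes, 28 rose and 3 fell (29 and 3 adjusted over the list alone), with a median of 1.00; DNAJB9 rose by 2.93, the sensor ERN1 by 2.36 and HSPA5 by 1.39 ± 0.0389. Of 25 NRF2 targets, 22 rose and 2 fell, also adjusted over the list alone, with AKR1C3 up by 2.94 and AKR1C1 by 2.42. The AKR1C1 value was 0.16 without shared probe sets (adjusted p = 0.238). Camera called these lists (adjusted p = 2.19e-13, 3.42e-13 and 3.02e-09, and 0.00204 for each with an estimated correlation).

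Cell division genes fell in MDA-MB-231 as well, with a median of -1.33 for G2/M, where 39 of 41 fell, and of -1.26 for S phase, where all 45 fell, both also adjusted over the list alone. HMMR fell by 3.85 ± 0.091 and the mitotic kinesin KIF20A fell by 2.37, and GINS2, a subunit of the replicative helicase, changed by -2.28 and POLE2 by -2.27. For GINS2 the mean of all probe sets changed by -1.326, and the value without shared probe sets was -0.21 (limma adjusted p = 0.0247). Camera gave an adjusted p = 5.5e-23 for both lists (0.00461 and 0.00204 with an estimated correlation). Of 39 ribosome biogenesis genes, 7 rose and 28 fell, also adjusted over the list alone, with WDR43 down at -1.20 and DDX10 up by 0.94 (adjusted p = 4.93e-06, and adjusted p = 0.163 with an estimated correlation). The actin 3'/5' ratio of the MDA-MB-231 arrays rose with 2DG, as given above, beside all of these groups and those that follow.

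The largest rises in MDA-MB-231 were PRSS35, a serine protease family member, by 6.73 ± 0.0868, RELN, the extracellular protein reelin, by 4.78 ± 0.0997, LINC00622 by 4.47 and the small GTPase RHOB by 4.13. GCNA rose by 3.71, TSC22D3 by 3.55, TMEM171 by 3.45 and PRRG4 by 3.39. Falls were led by HMMR, then DLEU2 (-3.50), the transcription factor E2F8 (-3.27), CDCA7 (-3.242), MGC12916 (-2.80), TIMM23B (-2.64), SP2-AS1 (-2.60) and the histone chaperone ANP32E (-2.57). The limma adjusted p of these 16 genes were at most 3.09e-09. The mean of all probe sets was 0.90 for RHOB and -1.86 for MGC12916, and without shared probe sets CDCA7 changed by -1.20 and DLEU2 by -0.615. Without shared probe sets TSC22D3 changed by 0.11 (adjusted p = 0.526).

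Genes of MAPK and inflammatory signalling rose in MDA-MB-231. Of 29 MAPK genes, 18 rose and 3 fell (19 and 3 adjusted over the list alone), with EGR1 up by 1.67 and EREG, a ligand of the epidermal growth factor receptor, by 1.57 (adjusted p = 0.000188, and adjusted p = 0.269 with an estimated correlation). Of 27 NF-kB and inflammatory genes, 15 rose and 3 fell, also adjusted over the list alone, with PTGS2, the inducible cyclooxygenase, up by 3.07 and CXCL8 by 1.91 (adjusted p = 0.0132, adjusted p = 0.0559 with an estimated correlation, and 0.0517 without shared probe sets). Of 39 autophagy and lysosome genes, 29 rose and 5 fell, also adjusted over the list alone, with MAP1LC3B up by 1.78 and NPC1 by 1.42 (adjusted p = 1.75e-06, and adjusted p = 0.163 with an estimated correlation).

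In MDA-MB-231, 6 of 22 glycolysis and glucose uptake genes rose and 15 fell, also adjusted over the list alone. The transporter SLC2A3 rose by 1.495, PFKFB2 fell by 1.24 and HK2 fell by 0.62 ± 0.057. The list passed at an adjusted p = 0.0133, with an adjusted p = 0.346 with an estimated correlation, 0.502 without shared probe sets and 0.0641 without dim genes. SLC2A1 fell by 0.35 ± 0.0375, but the change of its other probe set was 0.18 (adjusted p = 0.0774) and that of the mean of both -0.09 (adjusted p = 0.165). Another probe set of PFKFB2 had a change of 0.72. TXNIP rose by 1.88 ± 0.0329 and ARRDC4 by 1.91 ± 0.0493. Of 56 oxidative phosphorylation genes, 6 rose and 36 fell, also adjusted over the list alone, with ATP5PD at -0.88 and ATP5MC1 at -0.83 (adjusted p = 1.43e-05, and adjusted p = 0.294 with an estimated correlation). With the actin ratio as a covariate the counts were 2 and 34, and without shared probe sets ATP5PD changed by -0.12 (adjusted p = 0.206).

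YAP and TAZ targets went both ways in MDA-MB-231 too. Of 21 core targets, 6 rose and 10 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.151, median -0.15). The tissue factor gene F3 fell by 1.54, DOCK5 fell by 1.32, AMOTL2 fell by 0.48 ± 0.0341 and CCN2 fell by 0.45 ± 0.0502, while CCN1 rose by 0.17 ± 0.0466. ANKRD1 fell by 0.72 ± 0.204 (limma adjusted p = 0.00741), and vehicle replicate B deviated by -1.09 from the mean of the other 3 vehicle arrays. With the actin ratio as a covariate, the change of ANKRD1 was -0.09 (limma adjusted p = 0.763), but within groups that ratio varied mainly through replicate B. The fall kept its direction and call whichever array was left out. The conserved signature had 13 of 50 members that rose and 25 that fell (13 and 26 adjusted over the list alone), with HMMR down and NDRG1 up by 1.84 (adjusted p = 0.0132, adjusted p = 0.346 with an estimated correlation, and 0.0641 without dim genes). YAP1 fell by 0.28 and WWTR1 fell by 0.63 on their brightest probe sets. Other probe sets had changes of 0.98 for YAP1 and 1.49 for WWTR1, and the mean over all probe sets of a gene rose by 0.21 for YAP1 and 0.37 for WWTR1, so the direction of both genes depended on the probe set.

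The remaining lists were not called in MDA-MB-231. Aminoacyl-tRNA synthetases had 8 that rose and 7 that fell (8 and 8 adjusted over the list alone), with WARS1 at 1.31 and FARSB at -1.96 (adjusted p = 0.385). Pentose phosphate genes had 3 and 6, with RPE at -1.82 and PRPS1 at -0.89 (adjusted p = 0.112, and 0.021 without shared probe sets). Hexosamine and N-glycosylation genes had 13 and 16 (14 and 16 adjusted over the list alone), with ALG10 at -1.48 and GFPT1 at 1.20 (adjusted p = 0.578); another probe set of GFPT1 was at -0.70. Cholesterol genes had 7 and 9 (8 and 10 adjusted over the list alone), with PMVK at -1.47 and EBP at -1.39 (adjusted p = 0.432). Fatty acid synthesis had 3 and 8, and 5 and 8 without vehicle replicate B, with ME1 at 1.47 and SREBF1 at -1.07 (adjusted p = 0.252).

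The p53 targets had 10 and 10 in MDA-MB-231, with SESN2 at 1.64 and RRM2B at -1.24 (adjusted p = 0.999), and hypoxia and HIF targets 14 and 11, with DDIT4 at 1.92 and NDRG1 (adjusted p = 0.474). Interferon-stimulated genes had 14 and 8 (14 and 9 adjusted over the list alone), with IFIT2 at 1.54 and IRF9 at 1.18 (adjusted p = 0.384, and 0.021 without shared probe sets). Heat shock genes had 6 and 9, with DNAJB4 at 1.00 and HSPB1 at -0.80 (adjusted p = 0.485, and 0.0273 without shared probe sets). Extracellular matrix and integrin genes had 16 and 14, with the collagenase MMP1 at 2.22 and SDC1 at -2.14 (adjusted p = 0.474). Epithelial and basal markers had 11 and 9, with CLDN1 at 1.38 and KRT19 at -1.25 (adjusted p = 0.957), mesenchymal markers 9 and 2, with LOX at 0.61 and FN1 at 0.53 (adjusted p = 0.356), and luminal markers 3 and 6, with XBP1 at 1.94 and AGR2 at 1.59 (adjusted p = 0.385). Counts not given separately were the same adjusted over the list alone. The median of the synthetases and of the p53 targets was below 0 where the mean and the test lay above it. Without vehicle replicate B the median of the p53 targets was 0.02.

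Over all genes, 5039 were higher and 5018 lower with 2DG in MDA-MB-231, and 601 and 936 of these were strong calls. The median change of all genes was 0.0275. Camera called 6 lists up and 6 down, and 3 and 2 with an estimated correlation.

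**Figure D3:**
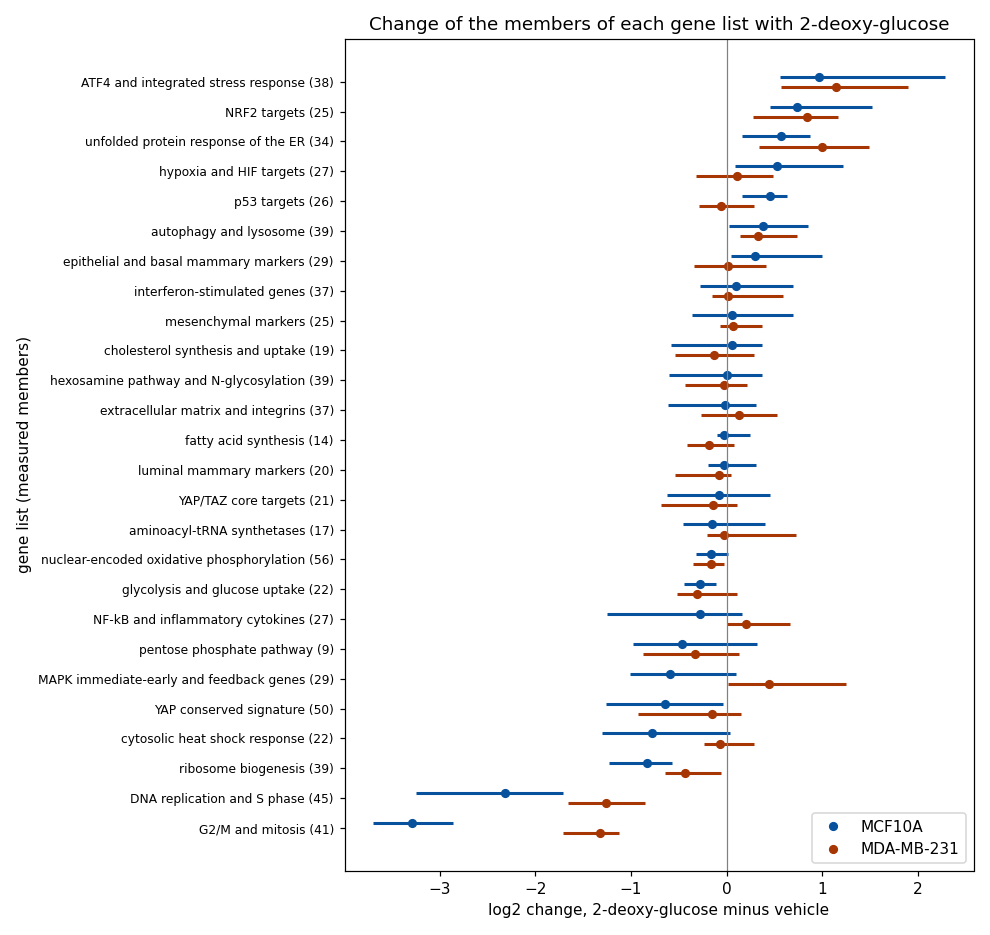
Median log2 change with 2DG of each gene list (points) and the quartiles over its members (lines) in MCF10A and MDA-MB-231, with the number of measured members in parentheses. The cell division lists lie lowest in both lines, with G2/M at -3.29 in MCF10A and -1.33 in MDA-MB-231, and the ATF4 list highest, at 0.97 and 1.15.

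The responses of the lines overlapped. Of the genes tested, 3020 were higher in both lines and 3151 lower in both, where independent lists of the same sizes would share 1461 and 1266. Another 917 were higher in MCF10A and lower in MDA-MB-231, and 709 the reverse, against 1455 and 1271 for independent lists. The direction was shared by 79.1% of the 7797 genes called in both lines. Strong calls shared were 258 upward, among them TSC22D3, TXNIP, ARRDC4, ATF3 and DDIT3, and 454 downward, among them HMMR, POLE2 and FARSB. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.54. No array was shared between these comparisons.

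The responses differed between the lines most in PRSS35, which rose in MDA-MB-231 and had a change of 0.03 in MCF10A (difference 6.70 ± 0.123), and in CXCL8 (6.17 ± 0.0834) and PTGS2 (5.42 ± 0.106), which fell in MCF10A and rose in MDA-MB-231. KBTBD8 differed by 5.38, MCM10 by 5.16 and RELN by 4.80. In the other direction, CACNA2D3 differed by -4.57, MYLK, the myosin light chain kinase, by -4.45, CAPN8 by -4.42, ABCG1 by -4.32 and PDK4 by -4.32. The limma adjusted p of these genes were at most 5.67e-12. The difference was 2.87 for MCM10 and -1.67 for ABCG1 without shared probe sets, and -1.46 for MYLK with the mean of all probe sets.

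Cell division genes fell less in MDA-MB-231: 40 of 41 G2/M members had a higher response there (median difference 1.90, adjusted p = 3.75e-30, and 0.00673 with an estimated correlation), and 39 of 45 S phase members, with 1 lower (median 1.42, adjusted p = 4.56e-20, and 0.00673), both also adjusted over the list alone. Ribosome biogenesis had 33 higher and 0 lower of 39 (median 0.49, adjusted p = 3.57e-11, and 0.0375), and the unfolded protein response 23 higher and 5 lower of 34 (median 0.43, adjusted p = 3.33e-05, and 0.0375), both also adjusted over the list alone. Heat shock genes had 16 higher and 3 lower, also adjusted over the list alone (median 0.55, adjusted p = 2.75e-05, and 0.0375), and NF-kB and inflammatory genes 15 and 3 (16 and 3 adjusted over the list alone; median 0.48, adjusted p = 0.000149, and 0.00911). MAPK genes had 22 higher and 5 lower, also adjusted over the list alone (median 1.19, adjusted p = 2.25e-08, and adjusted p = 0.063 with an estimated correlation). The conserved YAP signature had 27 higher and 12 lower (28 and 12 adjusted over the list alone; median 0.27, adjusted p = 0.000292, and adjusted p = 0.165 with an estimated correlation).

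Responses lower in MDA-MB-231 were those of the hypoxia and HIF targets, with 4 higher and 17 lower of 27 (median -0.50, adjusted p = 0.000558, and adjusted p = 0.238 with an estimated correlation), and the p53 targets, with 5 and 16 of 26 (median -0.30, adjusted p = 0.0049, and adjusted p = 0.21 with an estimated correlation). Epithelial and basal markers had 2 and 16 of 29 (median -0.28, adjusted p = 0.0016, and adjusted p = 0.123 with an estimated correlation) and luminal markers 0 and 10 of 20 (median -0.17, adjusted p = 0.0172, 0.0499 with an estimated correlation, and 0.0998 without shared probe sets; median -0.44 over 14 members without dim genes). These 4 counts were the same adjusted over the list alone. On vehicle, 22 of the 29 epithelial and basal markers were already lower in MDA-MB-231 and 2 higher (median -2.36). The p53 targets were lower there for 20 of 26 and higher for 4. RMA compresses changes of small signals, and a part of vehicle levels in these lower responses was not tested. The core YAP and TAZ targets had 7 higher and 11 lower (8 and 11 adjusted over the list alone) and were not called (adjusted p = 0.452), nor was the ATF4 list, with 14 and 18 (14 and 19 adjusted over the list alone; adjusted p = 0.668). Lists that were not called either were the NRF2 targets (9 and 14, adjusted p = 0.14, and 0.0445 with the mean of all probe sets), glycolysis (10 and 5, adjusted p = 0.165), extracellular matrix (18 and 13, adjusted p = 0.211), the synthetases (10 and 5, adjusted p = 0.26), fatty acid synthesis (2 and 6, adjusted p = 0.357) and the pentose phosphate pathway (3 and 5, adjusted p = 0.452), each the same adjusted over the list alone. Autophagy had 10 and 15 (14 and 18 adjusted over the list alone; adjusted p = 0.514), cholesterol 5 and 7 (6 and 7 adjusted over the list alone; adjusted p = 0.75) and mesenchymal markers 10 and 10 (adjusted p = 0.912). The hexosamine list (16 and 12, and 16 and 13 adjusted over the list alone), oxidative phosphorylation (20 and 20) and the interferon-stimulated genes (13 and 10) each had an adjusted p = 0.958. For the hexosamine list and oxidative phosphorylation, the median, mean and test differed in sign.

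Over all genes, 4401 responses were higher and 4664 lower in MDA-MB-231, with 736 and 1019 strong calls.

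On vehicle, the lines differed in epithelial and basal markers. MDA-MB-231 had lower SERPINB5, the serpin maspin, by -9.45 ± 0.099, CSTA by -8.99, S100A8 by -8.84, the basal keratin KRT14 by -8.72 and CDH1, which encodes E-cadherin, by -8.44 ± 0.0894, and lower NETO2, CD109 and BNC1 by -8.26, -7.98 and -7.93. It had higher EDIL3 by 9.93 ± 0.092, the chemokine receptor CXCR4 by 7.79, ANKRD1 by 7.76, the connexin GJA1 by 7.75, CEP15 by 7.61, KRT19 by 7.57, BCAT1 by 7.21 and SPANXB1 by 7.19. With the mean of all probe sets, these differences were -6.05 for SERPINB5, -5.03 for CD109, 4.71 for EDIL3, 4.34 for CEP15 and 3.83 for KRT19, and S100A8 differed by -1.90 without shared probe sets. Of 29 epithelial and basal markers, 2 were higher and 22 lower in MDA-MB-231, also adjusted over the list alone (median -2.36, adjusted p = 7.51e-11, and 0.0153 with an estimated correlation). The luminal markers, with 7 higher and 7 lower of 20 (adjusted p = 0.684), and the mesenchymal markers, with 13 and 10 of 25 (adjusted p = 0.615), were not called. Of 19 cholesterol genes, 1 was higher and 16 lower, also adjusted over the list alone (median -0.83, adjusted p = 5.13e-07, and 0.0451). Core YAP and TAZ targets were higher for 18 of 21 and lower for 3, also adjusted over the list alone (median 0.48, adjusted p = 1.26e-05, and adjusted p = 0.116 with an estimated correlation). The conserved YAP signature had 33 higher and 9 lower (33 and 10 adjusted over the list alone; adjusted p = 1.26e-05, and adjusted p = 0.123 with an estimated correlation).

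Also on vehicle, the G2/M list was higher in MDA-MB-231 for 33 of 41 members and lower for 3 (adjusted p = 3.44e-07, and adjusted p = 0.123 with an estimated correlation), and the MAPK list for 20 of 29 and lower for 6 (adjusted p = 0.000959, and adjusted p = 0.294 with an estimated correlation). The p53 targets were lower for 20 of 26 and higher for 4 (adjusted p = 1.26e-05, and adjusted p = 0.0939 with an estimated correlation), and NF-kB and inflammatory genes lower for 18 of 27 and higher for 6 (adjusted p = 0.000959, and 0.0329 with an estimated correlation). These counts were the same adjusted over the list alone. The synthetases were shifted up (adjusted p = 0.0285, and adjusted p = 0.305 with an estimated correlation), and the unfolded protein response (adjusted p = 0.0177, and adjusted p = 0.217), heat shock (adjusted p = 0.019, and adjusted p = 0.234) and NRF2 lists (adjusted p = 0.0318, and adjusted p = 0.207) down. The media of the lines differed, so these values compare line and medium together. Over all genes, 5776 were higher and 5305 lower in MDA-MB-231 on vehicle, with 1336 and 1225 strong calls.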

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

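The tests of RNA quality, vehicle level, single genes and shared members were devised after the patterns they address had been seen, and the actin covariate was chosen after seeing the data, whereas the splits of the arrays were planned.

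Of 676 groups of 4 arrays, 45 held an array that stood apart from the other 3 by Dixon's criterion, where chance alone gives about 34. In 11 of the 45 the other 3 arrays had the same value to 2 decimals, so rounding alone can set an array apart there and the excess over chance is uncertain. The values are deviations in log2 from the mean of the other 3 arrays. On MDA-MB-231 vehicle replicate B, the deviation was 0.66 for actin 3'/5' control ratio, 0.25 for GAPDH 3'/5' control ratio, 0.075 for the mean of the list glycolysis and glucose uptake, 0.10 for the mean of the list autophagy and lysosome, 0.15 for ABCG1 and -1.09 for ANKRD1. For the same array it was 0.083 for MCM10 and 0.36 for SDC1. On MCF10A 2DG replicate D, the deviation was -0.089 for the mean of the list cholesterol synthesis and uptake, -0.053 for AKR1C1, -0.02 for ARRDC4, -0.26 for CFAP53, -0.077 for DNAJB9 and -0.04 for HSPA5. For the same array it was -0.11 for LYAR, -0.32 for CDCA7, 0.04 for IFIT2 and -0.01 for SDC1. On MCF10A 2DG replicate C, the deviation was 0.052 for the mean of the list DNA replication and S phase, 0.17 for MMP9 and -0.067 for SAMD9. On MDA-MB-231 2DG replicate C, the deviation was 0.046 for the mean of the list mesenchymal markers, 0.12 for AMOTL2, 0.45 for BLNK, -0.51 for CXCL1 and 0.13 for F3. On MCF10A vehicle replicate B, the deviation was -0.14 for ACSS2, -0.19 for PDK4, -0.067 for HSPB1 and -0.10 for MAP1LC3B. On MDA-MB-231 vehicle replicate D, the deviation was 0.063 for ATP5MC1, -0.34 for CAPN8, -0.14 for EXO1 and 0.12 for OGT. On MDA-MB-231 2DG replicate B, the deviation was -0.12 for CCN1. On MCF10A vehicle replicate C, the deviation was 0.11 for FJX1, 0.16 for DDX10 and 0.23 for SLC2A3. On MCF10A vehicle replicate D, the deviation was -0.04 for PFKM. On MCF10A 2DG replicate A, the deviation was -0.01 for DDIT4 and -0.11 for SREBF1. On MCF10A 2DG replicate B, the deviation was -0.18 for RHOB and -0.08 for RRM2B. On MDA-MB-231 vehicle replicate A, the deviation was -0.10 for SLC2A3. On MDA-MB-231 2DG replicate A, the deviation was -0.13 for TMEM171.

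The response of 12 lists differed between the lines in camera, given as the median response of MDA-MB-231 minus that of MCF10A. The median difference was 0.27 for YAP conserved signature, 0.43 for unfolded protein response of the ER, 1.90 for G2/M and mitosis and 1.42 for DNA replication and S phase. It was 0.49 for ribosome biogenesis, 0.48 for NF-kB and inflammatory cytokines, 1.19 for MAPK immediate-early and feedback genes and 0.55 for cytosolic heat shock response. Lists with a lower response in MDA-MB-231 had -0.30 for p53 targets, -0.50 for hypoxia and HIF targets, -0.28 for epithelial and basal mammary markers and -0.17 for luminal mammary markers. With an estimated correlation, 6 higher and 1 lower response were still called. Those of the conserved YAP signature (adjusted p = 0.165), MAPK genes (0.063), p53 targets (0.21), hypoxia and HIF targets (0.238) and epithelial and basal markers (0.123) were not.

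Of the 127 genes named for a response to 2DG or for its difference between the lines, 112 responded differently in the lines (limma, adjusted over all genes). Of these, 74 differed by at least 1 and 17 had calls in opposite directions. Over all genes the share called for the difference was 45.8%. The rule picked large changes and large differences, so a higher share among the named genes follows in part from the choice. Among ATF4 and integrated stress response, the difference was -0.82 for ATF3, -1.48 for DDIT3, -2.14 for STC2, 4.35 for CTH and 1.498 for DDIT4. Among DNA replication and S phase, the difference was 3.37 for CCNE2, 5.16 for MCM10, 3.06 for POLE2, 3.87 for RRM2 and 1.62 for GINS2. Among G2/M and mitosis, the difference was 3.16 for BUB1 and 1.38 for KIF20A. Among MAPK immediate-early and feedback genes, the difference was -0.55 for EGR1, 0.70 for SPRY1 and 2.17 for EREG. Among NF-kB and inflammatory cytokines, the difference was 3.65 for CXCL1, 6.17 for CXCL8 and 5.42 for PTGS2. Among NRF2 targets, the difference was -1.36 for AKR1C1. Among YAP conserved signature, the difference was 1.15 for HMMR, 3.31 for SHCBP1 and 2.03 for THBS1. Among YAP/TAZ core targets, the difference was 0.27 for AMOTL2, 0.84 for CCN1, 1.93 for FJX1, 2.26 for NT5E, -0.85 for DOCK5 and -0.21 for F3. Among aminoacyl-tRNA synthetases, the difference was -0.48 for FARSB and -0.30 for WARS1. Among autophagy and lysosome, the difference was -1.02 for GABARAPL1, -1.005 for ULK1 and 0.94 for MAP1LC3B. Among cholesterol synthesis and uptake, the difference was -0.22 for ACAT2 and -0.85 for EBP. Among cytosolic heat shock response, the difference was -1.75 for CRYAB, 1.08 for HSPE1 and -1.36 for HSPB1. Among epithelial and basal mammary markers, the difference was -1.55 for ELF3, -2.51 for KRT16, 0.54 for CLDN1 and -1.15 for KRT19. Among extracellular matrix and integrins, the difference was 2.67 for MMP9, 0.90 for FN1, 4.62 for MMP1 and -1.42 for SDC1. Among fatty acid synthesis, the difference was -1.49 for ACSS2, 1.22 for ELOVL6, 0.78 for ME1 and -1.04 for SREBF1. Among glycolysis and glucose uptake, the difference was 1.66 for HK2, 0.41 for PFKM, -0.50 for SLC2A1, -1.07 for PFKFB2 and 1.09 for SLC2A3. Among hexosamine pathway and N-glycosylation, the difference was -1.08 for OGA, -0.54 for OGT and -1.22 for ALG10. Among hypoxia and HIF targets, the difference was 1.85 for ANGPTL4 and -0.84 for LOX. Among interferon-stimulated genes, the difference was -1.64 for RSAD2, -0.49 for SAMD9 and 0.47 for IFIT2. Among luminal mammary markers, the difference was -1.59 for AGR2. Among mesenchymal markers, the difference was -2.27 for S100A4 and -1.71 for ZEB2. Among nuclear-encoded oxidative phosphorylation, the difference was 0.73 for ATP5MC1, 0.24 for NDUFB3 and -0.33 for ATP5PD. Among p53 targets, the difference was -1.63 for SPATA18, -2.35 for TP53INP1 and -1.83 for RRM2B. Among pentose phosphate pathway, the difference was 0.27 for PRPS2, 0.80 for RPIA and -0.84 for RPE. Among ribosome biogenesis, the difference was 1.73 for LYAR, 1.00 for POLR1B and 1.28 for DDX10. Among unfolded protein response of the ER, the difference was 0.43 for DNAJB9, -0.47 for HERPUD1, 0.58 for HSPA5 and 0.82 for ERN1. Outside the lists it was -4.32 for ABCG1, -1.35 for ARRDC4, -4.12 for BLNK, -4.57 for CACNA2D3, -4.42 for CAPN8, -3.63 for CFAP53, 3.98 for DTL, 2.51 for EXO1 and -4.18 for KLRC3. Further such genes had -4.32 for PDK4, 3.25 for SPC25, -0.96 for TSC22D3, -0.71 for TXNIP, 0.38 for WWTR1, -0.19 for YAP1, 0.67 for CDCA7, -1.47 for DLEU2 and 1.16 for E2F8. Others had values of 1.43 for GCNA, 0.75 for LINC00622, -1.80 for MGC12916, 2.13 for PRRG4, 6.70 for PRSS35, 4.80 for RELN, 2.75 for RHOB, -1.03 for SP2-AS1 and -0.92 for TIMM23B. The remaining genes had 3.80 for TMEM171, 5.38 for KBTBD8 and -4.45 for MYLK. All of these values are those of the brightest probe sets. The count of probe sets with an opposite sign, given with the methods, covered only the largest differences. Other probe sets gave 0.04 and 0.075 for HK2, -0.75 for SPRY1, -0.065 for MAP1LC3B, -0.038 and 0.463 for FARSB and 0.075 for SREBF1. For CXCL8 and PTGS2 the other probe set gave similar values, 6.088 and 5.962.

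The cell division lists fell less in MDA-MB-231, with a median over 86 members of -1.31 beside -3.02 in MCF10A. With the actin ratio as a covariate, the median difference was 1.90 for G2/M (camera adjusted p = 3.92e-30) and 1.32 for S phase (adjusted p = 5.33e-20). In MDA-MB-231 the fall was -1.34 against vehicle replicate B alone beside -1.29 against the other 3 arrays. Within groups the ratio varied mainly in MDA-MB-231 vehicle (SD 0.331, and at most 0.0714 in the other groups), through replicate B. Both comparisons thus rest largely on that 1 array and argue only weakly against a shift of the 3'/5' ratio as the whole cause. Different vehicle levels are argued against by the 48 members whose vehicle means lay within 0.5, with a median difference of 1.53 and quartiles of 0.887 and 2.00. A difference between the lines in how 2DG acts on proliferation may remain, and line and medium cannot be separated by this design.

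The inflammatory and MAPK genes moved apart, with a median over 55 members of -0.40 in MCF10A and 0.27 in MDA-MB-231. With the actin covariate the median difference was 0.45 for NF-kB (camera adjusted p = 0.000311) and 1.14 for MAPK (adjusted p = 5.5e-08) at the preset correlation. The change in MDA-MB-231 was 0.32 against vehicle replicate B alone beside 0.26 against the others. Both comparisons rest largely on replicate B, so they argue only weakly against RNA quality as the whole cause. Without CXCL8, PTGS2, CXCL1 and SPRY4 the other 51 members still differed (median 0.69, camera p = 0.00871 with an estimated correlation and 2.79e-08 with the preset one), so a few genes do not carry the difference of the pooled lists alone. The MAPK list by itself was not called with an estimated correlation (adjusted p = 0.063). Different vehicle levels were not tested for these genes. On vehicle, 18 of 27 NF-kB genes were lower in MDA-MB-231 and 6 higher, and 20 of 29 MAPK genes were higher and 6 lower. The line, or its medium, may underlie the difference of the pooled lists, which was not tested.

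The conserved YAP signature was shifted down in both lines at the preset correlation but not with an estimated one (adjusted p = 0.0638 in MCF10A and 0.346 in MDA-MB-231), nor in MDA-MB-231 without dim genes (adjusted p = 0.0641). Of its members, 7 are in the cell division lists. Without them, 43 members had a median of -0.50 in MCF10A (camera p = 0.000205, but 0.0723 with an estimated correlation), so at the preset correlation those 7 genes were not the whole of the fall. Other genes of proliferation outside the cell division lists may remain among the 43, so a part played by proliferation was not excluded. In MDA-MB-231 the same 43 members had a median of -0.09 (p = 0.132, and 0.44 with an estimated correlation), so there the call may rest on the cell division genes, whose median was -1.45. A change in YAP activity itself was not tested.

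The counts of genes were compared with those from other groupings of the same arrays. In MCF10A, 1 of 35 splits of the 8 arrays, the real one, gave as many calls (10793, highest other 0), and the same held in MDA-MB-231 (1 of 35; 9764, highest other 0) and between the lines on vehicle (1 of 35; 10973, highest other 0). For the difference of responses it was 1 of 100 relabelings (9065, highest other 5526). Those relabelings mixed treated and untreated arrays within a line, so they do not test the difference by itself. The other splits of 8 arrays also mixed the groups compared. Mixing raises the residual variance, so the 0 calls of those splits are no independent measure of chance. The replicates were run in parallel, so neither result speaks to a repeat of the experiment.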

How the results depend on the processing

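The actin covariate, the list counts without MDA-MB-231 vehicle replicate B and the YAP signature without cell division genes were chosen after seeing the data, and the other alternatives were planned. All 266 alternative counts of genes stayed within 1.5 times the reported ones: with 2DG 4569 to 5858 higher and 3969 to 5328 lower in MCF10A, 3862 to 5135 and 4073 to 5153 in MDA-MB-231, and 3255 to 4564 and 3803 to 4740 for the difference. Without each array in turn these were 5461 to 5826 and 4819 to 5048, 4737 to 5054 and 4845 to 5008, and 4241 to 4511 and 4503 to 4634. On vehicle they were 5602 to 5812 and 5114 to 5344, and in both lines 2888 to 3091 and 3073 to 3137. List counts stayed at 7, 9, 6, 6, 8 and 4 whichever array was left out. With the filter on dim genes, 4 lists were shifted down in MDA-MB-231. The actin covariate gave 4077 higher and 4786 lower in MDA-MB-231, where 83.7% of the reported calls were called again in the same direction. With an estimated correlation, 3 lists were shifted up and 3 down in MCF10A, 3 and 2 in MDA-MB-231, and 1 list had a lower response in MDA-MB-231. By its construction, this test allows for members that move together. Without shared probe sets TSC22D3 in MCF10A was at -0.33 and SLC2A1 in MDA-MB-231 at 0.18. With the mean of all probe sets WWTR1 in MDA-MB-231 was at 0.37 and YAP1 at 0.21, and YAP1 in MCF10A was at 0.286 and called as a rise. With the actin covariate ANKRD1 was at -0.09 in MDA-MB-231, where it lost its call, and at 0.072 in MCF10A, where it was not called in either fit. Within groups that covariate varied mainly through MDA-MB-231 vehicle replicate B, the array that stood apart for ANKRD1. In MDA-MB-231 the gene kept its direction and call whichever array was left out, so RNA quality as the cause of its fall was not settled. The reversed values of TSC22D3, SLC2A1, WWTR1 and YAP1 come from other probe sets of the gene, and why the probe sets differ was not tested. Of 4620 values of named genes 4608 kept direction and call, 5 lost the call, 1 gained it and 6 changed sign. Many of these alternatives, such as leaving out an array of the other line, cannot move the log2 change within a line. The pooled count is therefore a weak measure of robustness. Most of the changes came with the other choices of probe sets. Of 1872 list tests 1795 kept both, 30 lost the call, 4 gained it and 43 changed the direction given by camera, which compares members with all other genes. None of the 43 was called in either fit, and the mean itself changed sign in 17 of them. In MCF10A the mean changes of these lists were 0.106 for the synthetases, 0.028 for cholesterol and -0.122 for fatty acid synthesis without shared probe sets, and 0.01 for the hexosamine list with the mean of all probe sets. In MDA-MB-231 the mean of all probe sets gave 0.001 for the hexosamine list, 0.019 for p53 targets and 0.024 for epithelial markers. Without shared probe sets these were -0.007 for the hexosamine list, -0.092 for p53 targets and -0.34 for hypoxia targets. The actin covariate gave -0.015 for p53 targets and -0.018 for epithelial markers, and the replicate block and ranks 0.038 for p53 targets. For the difference, values without shared probe sets were 0.104 for core YAP targets, -0.023 for fatty acid synthesis, 0.048 for interferon genes and 0.014 for mesenchymal markers. Interferon genes were at 0.043 with the mean of all probe sets and -0.001 with the block, and oxidative phosphorylation at 0.003 with centring and -0.01 on ranks. Without each array in turn, p53 targets in MDA-MB-231 lay at 0.023 to 0.061, and the difference at -0.034 to -0.01 for the hexosamine list, -0.02 to 0.001 for oxidative phosphorylation and -0.02 to 0.022 for interferon genes. The correlations of same-lettered deviations within lines were small, between -0.099 and 0.088 over 8 pairs, 0 over 0.1. The 3 arrays best matched to their own letter were all in MCF10A, where the correlations lay between 0.04 and 0.088. A weak pairing by letter is therefore not excluded there. With the replicate block the counts were 5689 and 4956, 4953 and 4944, 4324 and 4587, and on vehicle 5734 and 5282. A fit to only the 8 arrays compared gave no value for the difference, which needs all 16. RMA values carry no background call, which limits what can be said of dim genes.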

Other observations

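All tests in this part were chosen after the large rises of PDK4, TSC22D3, ABCG1 and ZBTB16 had been seen, and those 4 genes were left out of the lists tested. ZBTB16 rose by 4.08 in MCF10A and had a change of 0.07 in MDA-MB-231 (limma adjusted p = 0.512).

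Genes known as targets of FOXO transcription factors, which insulin signalling restrains, rose in MCF10A: 21 of 22 rose and 0 fell, with a median of 1.66. SELENOP rose by 3.02 ± 0.0646 (SE, n = 4 per group), the ubiquitin ligase FBXO32 by 2.50 ± 0.0726, the insulin receptor substrate IRS2 by 2.25 ± 0.047 and the repressor BCL6 by 2.29 ± 0.0372 (limma adjusted p at most 2.78e-14). In MDA-MB-231, 17 rose and 2 fell, with a median of 0.54; BCL6 rose by 1.91, TRIB1 by 1.70 and CCNG2 by 1.29, while CAT fell by 0.79 and INSR fell by 0.40. Targets of the glucocorticoid receptor had 11 of 15 that rose and 3 that fell in MCF10A, with KLF9 up by 2.50 and MAOA by 2.20, and 9 and 3 in MDA-MB-231, with DUSP1 up by 1.51 and FKBP5 down at -1.57. These values are those of the brightest probe sets. The mean of all probe sets was 1.217 for SELENOP, 1.252 for FBXO32 and 0.918 for KLF9 in MCF10A, and 0.473 for TRIB1, 0.804 for CCNG2, 0.776 for DUSP1 and -0.492 for CAT in MDA-MB-231. Dimmer probe sets had the opposite sign, at -0.06 for KLF9, -0.18 and -0.095 for TRIB1 and 0.13 for CAT.

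These rises may reflect FOXO activity, a hypothesis found and tested on the same data. The FOXO list was shifted up in camera in MCF10A (p = 2.08e-12, adjusted over the 6 tests 1.25e-11, and 0.00251 with an estimated correlation) and in MDA-MB-231 (p = 3.41e-06, adjusted 1.02e-05, and 0.0167). The list holds TXNIP and GABARAPL1, whose rises were known before. Glucocorticoid receptor targets passed too in limma's camera (p = 0.00315 in MCF10A, adjusted p = 0.0063, and 0.0167 with an estimated correlation; p = 0.00666 in MDA-MB-231, adjusted p = 0.00999, and 0.0201 with an estimated correlation), so these tests do not tell the explanations apart. Targets of the sterol receptor LXR did not pass in limma's camera (p = 0.464 and 0.573, adjusted p = 0.557 and 0.573, and 0.658 for both with an estimated correlation). Of 11 such targets, 3 rose and 2 fell in MCF10A, and 3 rose and 4 fell in MDA-MB-231.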
